A study of Tetrahymena thermophila with 4 samples.

How the data were processed

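Small RNA of Tetrahymena thermophila was sequenced in 4 libraries, 1 per group. Per the labels' protocols, RNA was taken from total RNA of TWI1 KO cells, or from IPs made with an anti-Twi1p antibody (wild-type cells) or an anti-HA antibody (strains with HA-Twi1p or HA-Twi1p-hAGO2Lmut). It was separated on a gel, and a fraction that included 26 to 32 nt was made into cDNA libraries. Per the labels' protocols, single reads of 36 bases (Illumina GAII) or 50 bases (HiSeq2000) were produced and filtered as in an earlier study. Which library was run on which instrument, the mapper and the genome build are not given in the sources used here. The protocols list adapters with random bases for multiplexed sequencing, but do not say which libraries used them, so a library or instrument batch cannot be separated from the groups. Only the TWI1 KO label gives a time, 3 h.

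The authors deposited read counts per length for each library, from 18 to 32 nt, with a last class written as over 33 nt. They are raw counts of filtered reads, not corrected for PCR duplicates. Shares were computed over the 26 to 32 nt fraction or over all reads, with exact Clopper-Pearson 95% intervals that cover counting error only.

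The authors deposited base composition as the percentage of sequences with A, C, G or U at each position, for each length from 24 nt. At lengths of 24 to 32 nt the 4 bases summed to at least 99.9% at each position. The percentages of these lengths are given to at least 10 decimals, which allowed the number of sequences behind them to be computed, as the smallest number that makes every percentage of a length class whole. One number did so, within 0.0001 of a whole count, in each of 36 classes. It was below the read count of the class in 35 of them and above it in 1, the 24-nt class of the Twi1p IP (422692 sequences, 218982 reads). The percentages therefore rest on another set of sequences than the length counts, and the files do not say which, or whether repeated reads were counted once. Exact intervals for positions 1, 27 and 29 of the 29-nt class were computed from these numbers. The classes of 33 and 34 nt were left out: the lowest sum of the 4 bases at a position was 0 in both HA libraries and as little as 25.1% in TWI1 KO. The authors deposited counts of TWI1 KO scnRNAs mapped to the LMR locus by mismatch position and length, and, for 29-nt scnRNAs of the Twi1p IP, a list of ddG values, which were rounded to 1 decimal here. The choice of the listed sequences, the energy model and the coordinates of the locus are not given in the sources used here.

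Before the data were examined, the 29-nt class was set as the main class, and 3 pairs of libraries were set for comparison: Twi1p IP minus TWI1 KO, HA-Twi1p-hAGO2Lmut IP minus HA-Twi1p IP, and HA-Twi1p IP minus Twi1p IP. The rule for what to name was set at the same time: positions 1, 27 and 29, the 20 combinations of position and base with the largest difference in each pair, the lengths from 26 to 32 nt, the 3 highest and 3 lowest mismatch positions, and the centre and extremes of ddG. No genes were measured. With 1 library per group no test across groups was made. Differences were given in percentage points and set beside those between the HA-Twi1p and Twi1p IPs. Interior averages were taken over positions 6 to 24, a range chosen after the data were seen.

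Strand complementarity was measured for 3′ overhangs of 0 to 6 nt. For overhang h in sequences of length L, position i was paired with position L − h + 1 − i. The root mean square difference between the share of each base and the share of its complement at the paired position was taken over all pairs. The procedure was tested on simulated 29-nt duplexes, 20000 per setting, and returned the simulated overhang in 5 of 5 settings with both strands kept and in 5 of 5 with 1 strand chosen by its first base. The simulated strands had a first-base preference for U like that of TWI1 KO and the same base shares at interior positions. The simulation does not cover complementarity without the outermost pairs. Alternatives were other denominators for length shares, the 28-nt and 30-nt classes, all lengths of 26 to 32 nt weighted by their reads, mean absolute differences, complementarity without the outermost pairs, log2 ratios of shares, mismatches without the last 3 positions, and the median and a 5% trimmed mean of ddG. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.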

Results

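Scan RNAs (scnRNAs) of the ciliate Tetrahymena thermophila are small interfering RNAs made by a Dicer enzyme during conjugation and bound by the Argonaute protein Twi1p. The series asked how Dicer production and Argonaute loading each shape the scnRNA population. It set scnRNAs held by Twi1p against scnRNAs of cells that lack TWI1, which cannot have been loaded into it. Small RNA was sequenced from 4 libraries. One held RNA recovered with endogenous Twi1p from wild-type cells by immunoprecipitation (IP). One held total small RNA of TWI1 knockout (KO) cells, labelled 3 h. The remaining libraries held RNA recovered with an anti-HA antibody from TWI1 KO strains that expressed Twi1p carrying the HA epitope tag (HA-Twi1p) or a mutant form named HA-Twi1p-hAGO2Lmut, whose change the labels do not describe. Each group had 1 library, so no difference could be set against the spread between replicates and no p-value was computed. The HA-Twi1p and Twi1p libraries, IPs of the tagged and untagged protein, served as the nearest measure of how far 2 libraries differed. They are not replicates, since strain, tag and antibody differed.

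The libraries held 32971715 reads for the Twi1p IP, 23143501 for TWI1 KO total RNA, 41260968 for the HA-Twi1p IP and 39107352 for the HA-Twi1p-hAGO2Lmut IP. At these depths the exact 95% binomial intervals of length shares were narrow, and they cover counting error only. The base composition percentages of 29-nt sequences rest on 3284899, 2896844, 5516539 and 5837526 sequences in the same order, fewer than the reads of that length.

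The first comparison asked whether loaded and unloaded scnRNAs had the same length. In every library the commonest length was 29 nt. Within the 26 to 32 nt fraction, 29-nt reads made up 32.4% of the Twi1p IP (95% interval 32.38 to 32.41) and 30.3% of TWI1 KO total RNA (30.31 to 30.35). Reads of 30 nt were also more frequent in the IP, at 24.8% against 22.8%. The mean length in this fraction was 29.09 nt in both libraries. The 2.06-point difference at 29 nt was smaller than the 2.56 points that separated the HA-Twi1p IP from the Twi1p IP, while at 30 nt the difference exceeded that between these IPs (-1.23 points). The order at 29 nt depended on the denominator: it was 6.57 against 3.42 points over all reads and 1.44 against 0.78 over 27 to 30 nt. As a ratio of shares, shorter reads separated the libraries more: 23-nt reads were 5.79% of all TWI1 KO reads and 0.466% of Twi1p IP reads, a ratio of 12.43. The 26 to 32 nt fraction held 79.1% of TWI1 KO reads, 94.3% of Twi1p IP reads, 97.2% of HA-Twi1p IP reads and 97.3% of HA-Twi1p-hAGO2Lmut IP reads.

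**Figure D1:**
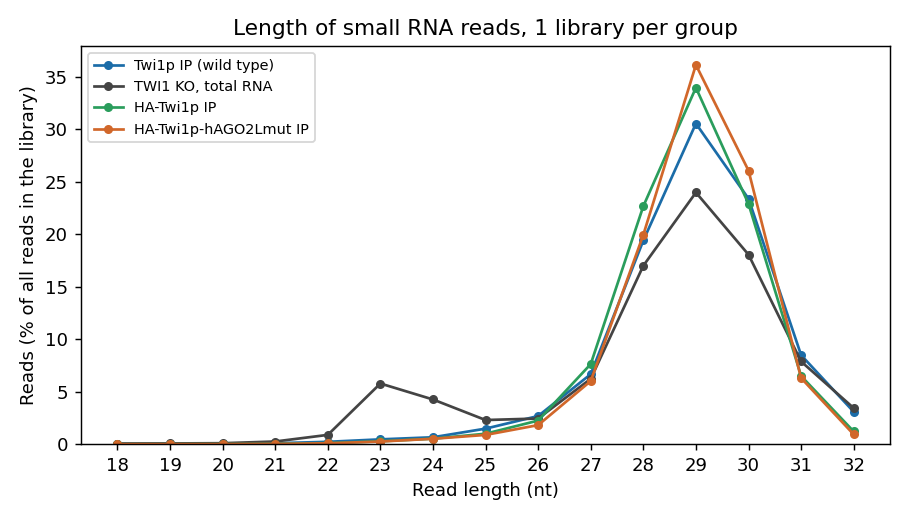
Reads of each length (x axis, nt) as a percentage of all reads in the library (y axis), with 1 line per library and IP standing for immunoprecipitate. All 4 lines peak at 29 nt, and TWI1 KO total RNA has a further peak at 23 nt, where it reaches 5.79%.

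The second comparison asked how the sequences of loaded scnRNAs differed from those of unloaded ones. U was the commonest first base in both, but it stood at 93.3% of 29-nt sequences in the Twi1p IP (95% interval 93.27 to 93.32) and 66.2% in TWI1 KO total RNA (66.13 to 66.23), 27.1 points apart. The other first bases were scarcer in the IP. A at position 1 was 3.77% against 23.5%, C was 2.01% against 6.11% and G was 0.93% against 4.26%. At position 27, the third from the 3′ end, the order was the other way: A was 52.0% in the IP and 63.5% in TWI1 KO, while U was 27.9% against 20.6%. In a duplex with 2-nt 3′ overhangs, which Dicer enzymes leave, position 27 of one strand pairs with position 1 of the other.

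Among the 116 combinations of position and base, 3 differed between the Twi1p IP and TWI1 KO by more than 8.36 points, the largest difference between the HA-Twi1p and Twi1p IPs. They were U and A at position 1 and A at position 27. At 28 nt the IPs of tagged and untagged Twi1p differed by up to 11.93 points, which U and A at position 1 exceeded (28.96 and -21.11) and A at the third position from the 3′ end did not (-11.14). At 30 nt they differed by up to 5.24 points, which 8 of 120 combinations exceeded, also A at position 30, U at positions 28, 2 and 7, and G at position 2. At 31 nt A at position 31 exceeded it besides U and A at position 1. The next differences at 29 nt were U at position 27, 7.31 points higher in the IP, U at position 2 (32.7% against 26.9%), A at position 29 (27.19% against 21.99%) and G at position 2 (16.6% against 21.6%). U was higher in the IP at 26 of 29 positions and A at 4 of 29. Also among the 20 largest differences, U at position 7 was 4.54 points higher in the IP, A at position 5 was 37.7% against 42.0%, and at position 20 A was 31.20% against 34.99% while U was 40.4% against 36.7%. Over positions 6 to 24, U averaged 38.4% ± 1.20 (SD over 19 positions) and A 33.3% ± 1.34 in the IP. In TWI1 KO the same averages were 36.0% ± 1.64 and 35.2% ± 0.90.

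The first-base difference was in the same direction at each of the 7 lengths from 26 to 32 nt, where U at position 1 was 18.2 to 29.5 points higher in the Twi1p IP. A at the third position from the 3′ end was lower in the IP at all 7 lengths, with differences of -11.56 to -7.50 points. Only at 29 and 30 nt did this exceed the largest difference, over all positions and bases, between the IPs of tagged and untagged Twi1p. First-base U exceeded that largest difference at all 7 lengths and first-base A at all but 32 nt (-14.73 against 16.75 points). For A at the third position from the 3′ end itself, HA-Twi1p minus Twi1p was -1.55 to 3.39 points. The fall of this A from TWI1 KO was larger than that at all 7 lengths. The HA-Twi1p IP, the other IP of unmutated Twi1p, had 91.7% U at position 1 and 54.8% A at position 27, so it lay on the same side of TWI1 KO for both. IP, genotype and loading changed together in this comparison. The last base was U in 51.9% of Twi1p IP sequences and 53.9% of TWI1 KO sequences.

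**Figure D2:**
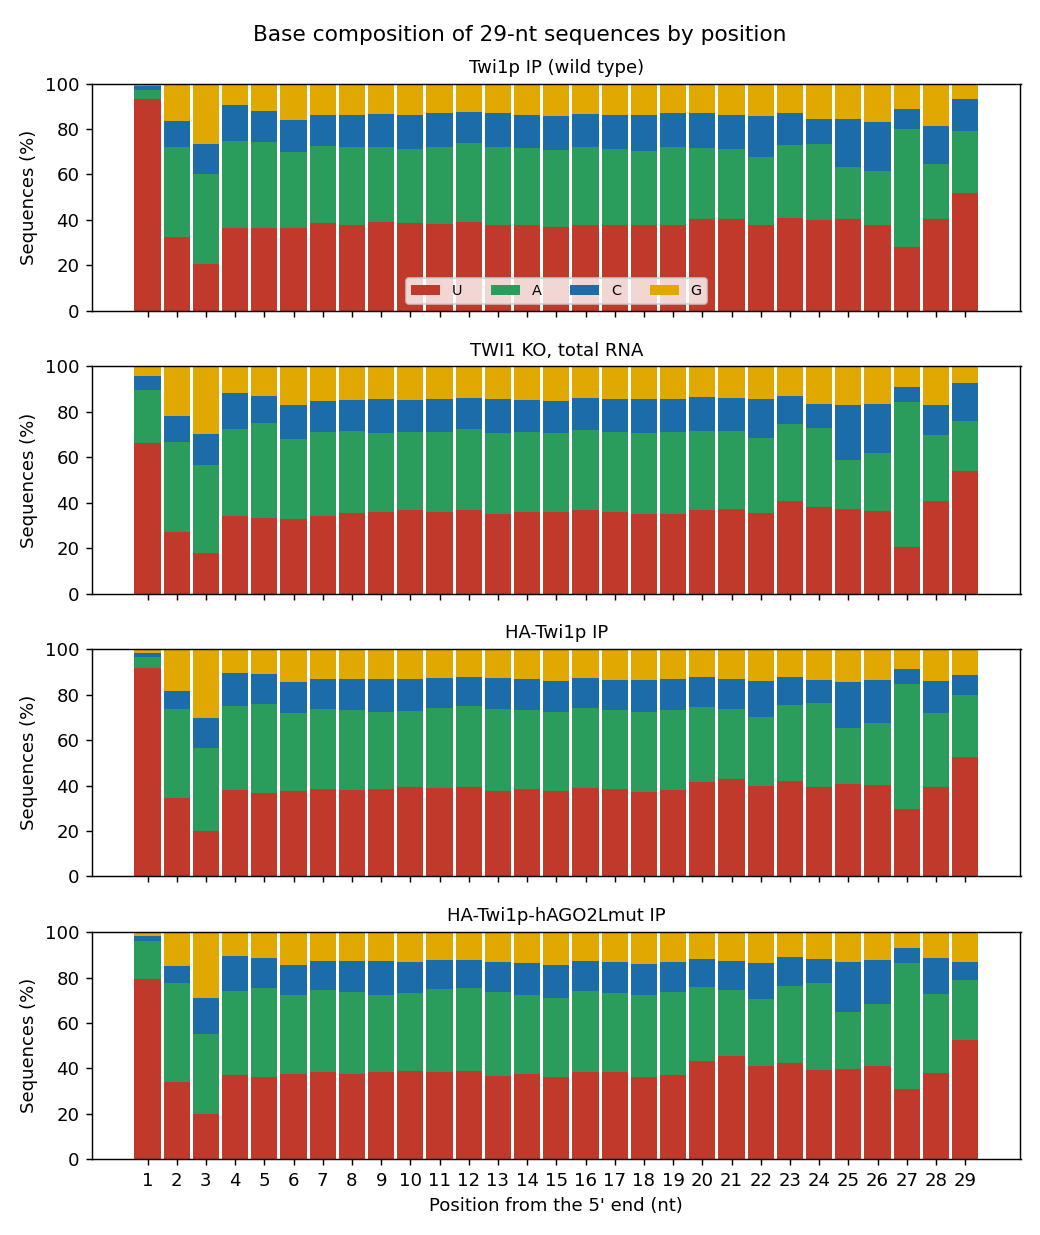
Percentage of 29-nt sequences (y axis) with U, A, C or G at each position from the 5′ end (x axis), as stacked bars with 1 panel per library and IP standing for immunoprecipitate. U fills 93.3% of position 1 in the Twi1p IP and 66.2% in TWI1 KO total RNA, where A at position 27 reaches 63.5%.

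The third comparison asked whether each library looked like both strands of Dicer duplexes. If both strands are present equally, the share of a base at one position equals the share of its complement at the paired position. For 29-nt sequences of TWI1 KO, the root mean square departure from this equality was 1.56 percentage points at an assumed 3′ overhang of 2 nt. It was 6.45 points at 5 nt, the next lowest of the overhangs from 0 to 6 nt. U at position 1 (66.2%) and A at position 27 (63.5%) differed by 2.64 points there, and A at position 1 (23.5%) and U at position 27 (20.6%) by 2.82 points. The lowest departure also fell at 2 nt in the IPs, but it was 7.59 points for Twi1p, 7.12 for HA-Twi1p and 5.23 for HA-Twi1p-hAGO2Lmut. In the Twi1p IP, U at position 1 exceeded A at position 27 by 41.3 points. With the outermost pair at each end left out, the departure at 2 nt was 1.42 points in TWI1 KO, against 3.81 at 5 nt. It was 3.67 in the Twi1p IP, whose lowest value, 3.54, then fell at 5 nt, and in the other IPs 2 and 5 nt were close (3.68 and 3.94 for HA-Twi1p, 3.64 and 3.67 for the mutant).

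**Figure D3:**
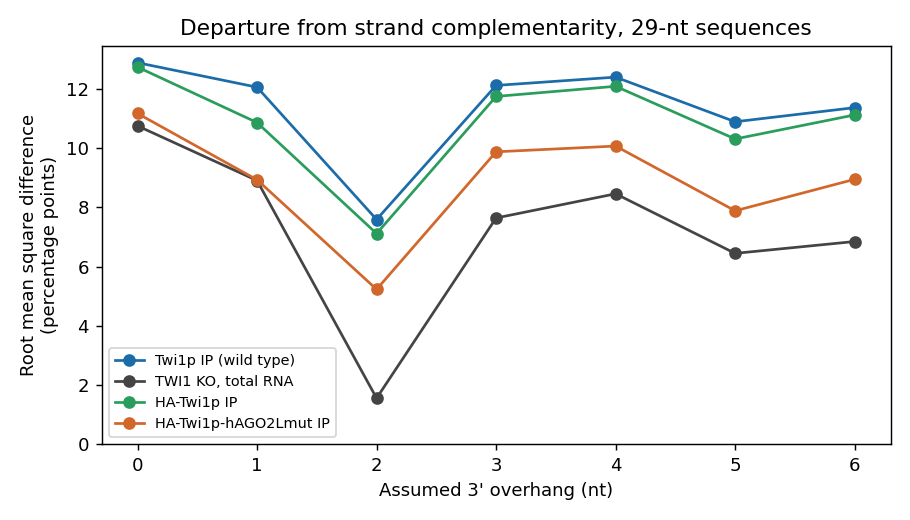
Root mean square difference, in percentage points (y axis), between each base's share and its complement's share at the paired position of 29-nt sequences, for assumed 3′ overhangs of 0 to 6 nt (x axis), with 1 line per library. All 4 lines are lowest at 2 nt, at 1.56 points in TWI1 KO total RNA and 7.59 points in the Twi1p immunoprecipitate.

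The fourth comparison set the mutant against its tagged parent protein. First-base U was 79.4% of 29-nt sequences in the HA-Twi1p-hAGO2Lmut IP and 91.7% in the HA-Twi1p IP, a difference of -12.25 points. A at position 1 was 16.8% against 5.02%, a ratio of 3.35 that depended on length (2.59 at 28 nt and 4.25 at 30 nt). C at position 1 was 2.23% against 1.55% and G was 1.52% against 1.74%. At 29 nt, these values for U and A were the only 2 of 116 combinations beyond the 8.36 points that separated the IPs of tagged and untagged Twi1p. U at position 1 was lower in the mutant at all 7 lengths from 26 to 32 nt, by 11.4 to 13.3 points. This exceeded the largest difference between the unmutated IPs at 28 nt (-12.89 against 11.93 points), 29, 30 and 31 nt, but not at 26 nt (-11.36 against 15.38), 27 nt (-12.58 against 14.03) or 32 nt (-13.32 against 16.75). The rise of A at position 1 exceeded that largest difference only at 28, 29 and 30 nt, and at 31 nt it was 11.72 against 11.81 points. Set against the difference in this A itself between the unmutated IPs, the rise was larger in size at all 7 lengths. It was 8.98 against 6.21 points at 26 nt, 11.80 against 1.25 at 29 nt and 12.07 against -5.00 at 32 nt. For U at position 1 itself, the fall was larger from 27 nt (-12.58 against -12.41) to 32 nt, but not at 26 nt (-11.36 against -15.38). A at position 27 was nearly level, at 55.6% in the mutant and 54.8% in HA-Twi1p, and this 0.81-point difference was smaller than the 2.79 points between the HA-Twi1p and Twi1p IPs. For A at the third position from the 3′ end, the difference was positive at 2 of 7 lengths. It was larger in size than that between the unmutated IPs at 31 nt (-1.42 against -0.71) and 32 nt (-4.30 against -1.55), but not at the other lengths.

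Away from position 1 the mutant differed less. A at position 2 was 43.8% against 39.5%, G at position 2 was 14.8% against 18.6%, C at position 3 was 15.6% against 12.9% and U at position 21 was 45.4% against 42.7%. Of the 20 largest differences, 17 lay in positions 1 to 3 or 24 to 29, and the median over all 116 was 0.53 points. The mutant had more 29-nt reads (37.16% against 34.96% of the 26 to 32 nt fraction) and 30-nt reads (26.8% against 23.6%), and fewer 28-nt reads (20.5% against 23.3%). Between the HA-Twi1p and Twi1p IPs the difference was larger at 29 nt (2.56 against 2.20 points), about as large at 28 nt (2.76 against -2.82) and smaller at 30 nt (-1.23 against 3.24). Over 27 to 30 nt the order at 29 nt was the other way (0.78 against 2.02 points).

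The IPs of tagged and untagged Twi1p differed chiefly at the ends. A at position 28 was 32.6% in the HA-Twi1p IP and 24.2% in the Twi1p IP. C at position 29 was 8.94% against 14.2%, G at position 29 was 11.3% against 6.69%, and C at position 2 was 7.56% against 11.4%. TWI1 KO total RNA lay nearer to the Twi1p IP for the last 3 of these, at 16.997%, 7.11% and 11.5%, and the mutant IP nearer to HA-Twi1p, at 8.30%, 12.998% and 7.42%. Of the 20 largest differences, 16 lay in positions 1 to 3 or 24 to 29. For U at position 1, HA-Twi1p minus Twi1p was -1.61 points at 29 nt and ranged from -15.38 to 9.57 points over 26 to 32 nt.

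Mismatches to the genome were tabulated for TWI1 KO alone, as the number of scnRNAs of each length that mapped to the locus named LMR with up to 2 mismatches. Counts were highest at the ends of the molecules. For 29-nt scnRNAs, position 29 had 2202 (5.33% of the 41334 summed over positions, exact 95% interval 5.11 to 5.55), position 2 had 1951 (4.72%) and position 1 had 1760 (4.26%). The lowest counts were 1064 at position 14 (2.57%, 2.42 to 2.73), 1216 at position 17 and 1217 at position 15. The last position exceeded every interior position, here those from position 4 to the fourth from the 3′ end, in all 9 length classes from 24 to 32 nt, by factors of 1.39 to 3.39 over the interior median. Position 1 exceeded every interior position in 7 of 9 classes. The table does not say whether perfect matches enter each value, and a molecule with 2 mismatches may be counted at both positions, so these intervals are approximate.

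**Figure D4:**
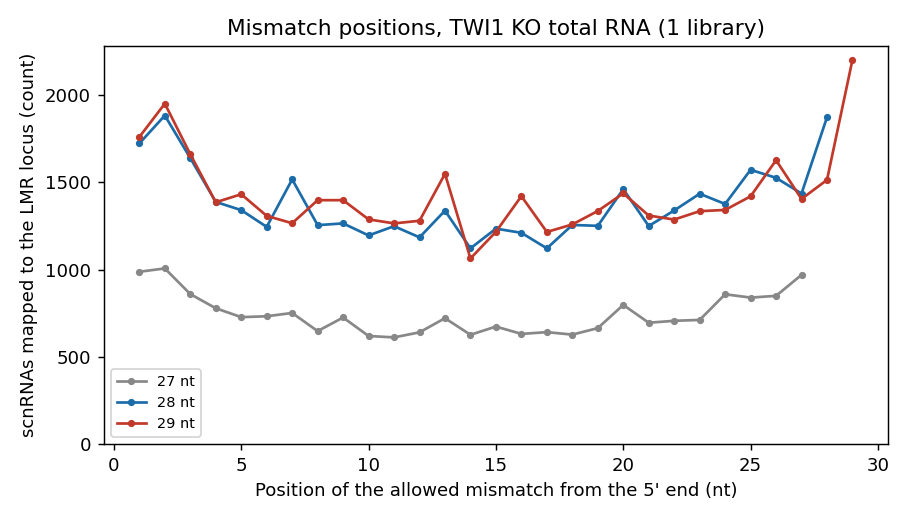
Number of TWI1 KO scnRNAs mapped to the LMR locus (y axis) by the position of the mismatch from the 5′ end (x axis), for lengths of 27, 28 and 29 nt in 1 library. The 29-nt line runs from 1760 at position 1 to a low of 1064 at position 14 and 2202 at position 29.

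The stability of the duplex ends was given for 4179 29-nt sequences of the Twi1p IP, as the difference ddG between the 5′ ends of guide and passenger strands in a modelled duplex. Strand choice by end stability would shift these values to one side of 0. The mean was -0.09 ± 2.06 (SD over sequences), with a standard error of 0.03, and the median was 0. Values below 0 made up 49.2%, values above 0 made up 46.2%, and 4.55% were at 0. Among the values other than 0, 51.6% were below 0 (exact 95% interval 50.003 to 53.1). The middle 90% ran from -3.40 to 3.20, and the extremes were -6.4 and 7.2. The energy unit and the direction of subtraction are not stated, and sequences of one library are not replicates.

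**Figure D5:**
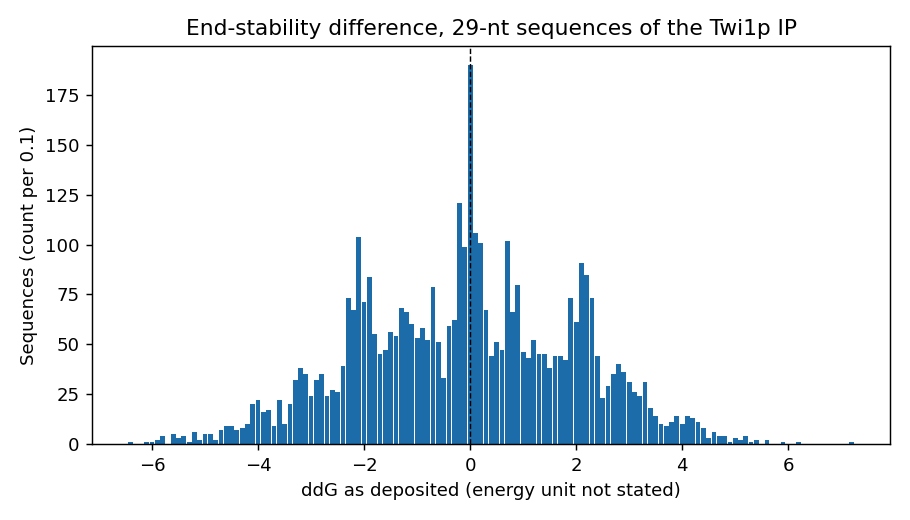
Number of 29-nt sequences of the Twi1p immunoprecipitate (y axis, per step of 0.1) by the deposited ddG value (x axis, energy unit not stated), with a dashed line at 0. The values spread almost evenly around 0, with 2057 below it, 1932 above it and 190 on it.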

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

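The tests in this part were chosen after the results were seen, and each spread used is the difference between the IPs of tagged and untagged Twi1p, which are 1 library each.

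A peak of 23-nt reads, 5.79% of all reads, appeared in TWI1 KO total RNA outside the 26 to 32 nt fraction on which the length comparison rests. The share was 0.466% in the Twi1p IP, 0.281% in the HA-Twi1p IP and 0.258% in the HA-Twi1p-hAGO2Lmut IP. Shortened scnRNAs that thinned out steadily below 29 nt would leave fewer 23-nt than 25-nt reads, but TWI1 KO had 2.51 times as many. This ratio is part of the peak as seen, and it argues only against steady shortening as the whole source. A size class that Twi1p does not bind is a candidate source: the 23-nt share was at least 12.43 times that of any IP, though other short reads were also more frequent in TWI1 KO, at 9.99 to 23.96 times at 18 nt and 6.42 to 8.20 times at 24 nt. It cannot be told apart from an effect of the knockout, since the only total RNA library was also the only one without Twi1p, and the composition tables start at 24 nt.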

How the results depend on the processing

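No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. All 57 alternatives were set before the data were examined; 19 gave the same result, 38 moved it and none reversed it. For shares of U and A any change in the printed value counts as a move, however small; for the largest difference between 2 libraries, a change of position or base does, so 28.96, -12.89 and 11.93 points at 28 nt count as the same. The 29-nt share over all reads was 30.56% (Twi1p IP), 23.99% (TWI1 KO), 33.98% (HA-Twi1p) and 36.15% (mutant), and over 27 to 30 nt it was 38.17%, 36.74%, 38.96% and 40.98%; each changed the order of at least 1 pair of differences between libraries. First-base U, in the same order, was 92.62%, 63.66%, 86.63% and 73.75% at 28 nt, 93.32%, 66.69%, 94.22% and 82.23% at 30 nt, and 92.09%, 64.94%, 89.62% and 77.85% over all lengths weighted by reads. A at the third position from the 3′ end was 46.56%, 57.69%, 49.62% and 49.21% at 28 nt, 53.58%, 64.83%, 55.40% and 56.20% at 30 nt, and 50.05%, 60.45%, 52.22% and 52.83% over all lengths. The IPs of unmutated Twi1p stayed above TWI1 KO for first-base U and below it for this A in each of these settings. Shares were judged library by library, so a change of sign between libraries is not counted as a reversal: at this A the mutant minus HA-Twi1p was 0.81 points at 29 nt and -0.41 at 28 nt. A largest difference that changed sign together with its base also counts as a move. The absence of reversals thus says little about how firm the results are. The best overhang moved from 2 to 5 nt for the Twi1p IP without the outermost pairs, and was 2 nt in the other 15 alternatives, narrowly so for the HA libraries without those pairs. On a log2 ratio scale the largest difference lay elsewhere: A at position 1 for the Twi1p IP against TWI1 KO (-2.64) and for the mutant against HA-Twi1p (1.74), and G at position 1 for HA-Twi1p against Twi1p (0.91). Without the last 3 positions, the highest mismatch count was at position 2 (5.39%). The median of ddG was 0.00, against a mean of -0.09.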

Other observations

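The tests in this part were chosen after the results were seen, as were the positions named in this paragraph. Besides position 1, the 29-nt sequences carried paired base preferences near both ends in all 4 libraries. G at position 3 was 29.6% in TWI1 KO, 26.7% in the Twi1p IP, 30.5% in the HA-Twi1p IP and 29.1% in the mutant IP. Its partner in a duplex with a 2-nt overhang, C at position 25, was 24.5%, 21.1%, 20.3% and 22.1%. For comparison, G averaged 14.6% and C 14.2% over positions 6 to 24 of TWI1 KO. U at position 3 was low, at 17.78%, 20.78%, 19.97% and 20.08%, as was its partner A at position 25, at 21.59%, 22.98%, 24.75% and 24.79%.

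The preference for a first-base U depended on length more in the HA libraries than in the others. In the HA-Twi1p IP it went from 65.7% at 26 nt to 95.1% at 31 nt, and in the mutant IP from 54.3% to 82.7%. In the Twi1p IP it was 81.1% at 26 nt and 91.3% at 31 nt, and in TWI1 KO 55.7% and 65.9%. At 26 nt the mutant IP was thus -1.36 points from TWI1 KO, while it was 13.25 points above it at 29 nt. The mismatch sums over positions came to 0.744% of the 29-nt reads of TWI1 KO but 0.122% of the 30-nt reads, with 0.127% at 31 nt and 0.124% at 32 nt. From 24 to 28 nt they came to 1.11%, 1.68%, 1.91%, 1.39% and 0.98%. These are not mismatch rates, since the sums count scnRNAs mapped to the LMR locus and the reads are those of the whole library.

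Loaded scnRNAs had more U at position 1 and less A at position 27 than TWI1 KO total RNA, and 3 simple explanations were set against the values, the first and last of them against the lower A itself, which was part of the pattern as seen. Dilution of TWI1 KO by reads without a base preference would lower both, but A at position 27 was at least 7.97 points higher there than in any IP, against a spread of 2.79. Choice of 1 strand per duplex, with every duplex loaded, would keep the sum of both shares. The sum was 129.72 in TWI1 KO, 145.27 in the Twi1p IP and 146.45 in the HA-Twi1p IP, a difference of at least 15.55 points. The spread of 1.18 is small partly because U and A differed in opposite directions between these IPs (-1.61 and 2.79 points). At the other lengths the difference exceeded its spread except at 26 nt (5.89 against 11.99). It was 12.38 against 9.41 at 27 nt and 9.07 against 8.02 at 32 nt. The mutant IP was not part of this test. Its sum was 135.00 at 29 nt and 138.43 at 30 nt (131.52 in TWI1 KO). At 28 nt it was 122.96 against 121.35 in TWI1 KO, and at 26, 27 and 32 nt it was lower than in TWI1 KO. Retention of single strands by their own first base, with duplex ends independent, would leave A at position 27 at its TWI1 KO level, but it was at least 8.78 points lower in the IPs of unmutated Twi1p. Each explanation was weighed alone, so these values do not exclude strand choice combined with dilution of TWI1 KO. Strand choice together with a preference for duplexes with U ends may also account for the pattern. Linked duplex ends and differences of genotype, time or library preparation stay open as well, and none of these was tested.

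To explain the higher A at position 1 in the mutant IP, unbound scnRNAs carried into it were considered, with TWI1 KO standing for them. At C of positions 2 and 29, TWI1 KO lay nearer to the Twi1p IP and the mutant nearer to HA-Twi1p. A departure from a mixture thus cannot be told apart from a difference between preparations. To give the observed U, unbound scnRNAs would have to make up 48.0% of a mixture with the HA-Twi1p IP. That mixture would give 6.69% C plus G at position 1, where 3.75% was observed. This 2.95-point shortfall exceeded the spread of 0.36 at 29 nt. At 30 nt it was 2.91 against 0.67, and at 28 nt it stayed within the spread (2.31 against 2.45). The 0.36 is small partly because C and G differed in opposite directions between the unmutated IPs (-0.45 and 0.81 points). A at the third position from the 3′ end fell short of the mixture by more than its spread at 28 nt (4.94 against 3.07), 29 nt (3.41 against 2.79) and 30 nt (3.31 against 1.82). Other lengths were not tested. A loss of first-base preference that raised A, C and G by the same factor was considered next, and unequal factors were not tested. Such a loss would give equal ratios, but at 29 nt the ratio of mutant to HA-Twi1p was 3.85 times larger for A than for G. The same ratios between the unmutated IPs differed by at most 2.43 times for any pair of these bases and 1.41 times for A and G. At 30 nt A over G was 4.77 against 1.35, but at 28 nt 2.73 lay between the 1.65 for A and G and the 3.01 for any pair. At 29 nt A over C, at 2.33, exceeded the 1.72 for A and C but lay within the 2.43 for any pair. At 30 nt A over C was 2.87 against 1.35, and at 28 nt it was 1.80 against 1.83. Thus 28 nt does not exclude an equal loss by the spread for any pair, while the 2.73 was beyond the spread for A and G. G at position 1 was 3.41% in the mutant IP and 3.60% in the HA-Twi1p IP at 28 nt. A loss shared by A and C stays open at 28 nt and, by the spread for any pair, at 29 nt. A candidate explanation that stays open is that the mutation lets Twi1p accept A as well as U, which 1 library of each protein cannot separate from a difference between preparations.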
